A study of Homo sapiens with 8 samples.

How the data were processed

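The arrays measured total RNA of H4 cells that was labelled with biotin and hybridised to Affymetrix Human Genome U133 Plus 2.0 arrays, 1 array per sample. There were 2 samples of control cells and 2 samples of cells transfected with Myc-tagged aSyn. Cells were grown in DMEM with fetal bovine serum and transfected with Fugene, per the labels' protocols. The deposited table has 8 columns, 4 of RMA and 4 of MAS5, and the labels give the same 4 samples in both. Each RMA column had its highest rank correlation with the MAS5 column of the same label, from 0.9 to 0.908. The MAS5 columns were therefore treated as a second summary of the same arrays and never as extra replicates. RMA values were deposited on a log2 scale, background corrected and quantile normalized between arrays as RMA does; RMA is named in the submitters' processing notes, and its version is not given in the sources used here. MAS5 values were deposited as intensity on a linear scale, also named in the submitters' processing notes, and each column has a 2% trimmed mean of 100.01, while the scaling target and the version are not given in the sources used here. Detection calls were not used here.

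The table holds 54675 probe sets, of which 62 AFFX control probe sets were left out of the tests and read only for RNA quality. Genes were named from the platform annotation and updated by gene identifier through a table of human genes (assembly GRCh38.p14), used for names and neighbours only. Of the 54613 probe sets tested, 41091 had 1 gene symbol, 1801 had several and 11721 had none; 41037 of the 41091 matched the gene table. A gene was read from 1 probe set, not one ending in _x_at where it had another, and then the one with the highest mean RMA value over the 4 arrays, which gave 19775 genes. Where probe sets of a gene disagree, a value in the text is that of this probe set.

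Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the RMA log2 values of the 4 arrays, group as the only term, 2 residual degrees of freedom and 3.71 prior degrees of freedom), two-sided, with Benjamini-Hochberg adjustment over the 54613 probe sets and a threshold of 0.05. All adjusted p-values of single genes come from this fit. Differences are aSyn minus control in log2, with the standard error of the moderated fit. Probe sets that lay apart by 1.5-fold in every pair of arrays were counted without a test, beside the same count in the other 2 ways to split the 4 arrays. The 34 gene lists, with 1128 entries of which 1022 had a probe set, were tested with camera at a preset correlation of 0.01, adjusted over the 34 lists, and again with an estimated correlation and with fry. Fry tests whether a list's genes move, on balance, in a shared direction, and camera compares the list with other genes. With an estimated correlation 0 of the 17 lists that passed kept an adjusted p below the threshold.

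The lists, the tests and the alternatives were fixed before the data were examined, and so was the rule for named genes. It took the 12 largest rises and the 12 largest falls among genes past the threshold whose aSyn arrays both lay above or both below the control arrays and whose mean RMA value was at least 5. It also took up to 4 members of each list with the largest absolute difference and a mean of at least 5, and members of the cell type marker lists with a mean of at least 8. The rule also named the transfected gene, which is not analysed here. Alternatives were MAS5 values as log2(value + 1), the same after quantile normalization, MAS5 as log2(value + 16), the replicate number as a block, leaving out each array in turn (the lone array of its group is then assumed to vary like the other group), a variance prior with trend and robust settings, the probe sets above the median mean value, a fold threshold of 1.5, and the median level of all probe sets of a gene in each array.

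The procedure was tested on simulated data made from the 4 arrays with 200 of the 54613 probe sets changed. It recovered 44.8% of changes of 1.5-fold, 98.5% of changes of 2-fold and 100% of changes of 4-fold, with 11 of its 173 calls (6.36%) on unchanged probe sets. It made 0 calls when nothing was changed. A list shifted in the simulation was recovered by camera with the preset correlation, with 0 of the other lists past the threshold. With an estimated correlation it had an adjusted p of 0.0817, so the shift was missed. The simulated noise was drawn for each probe set by itself, so genes were uncorrelated. Estimated correlations of the real lists ran from -0.058 (astrocyte markers) to 0.589 (interferon response). The simulation therefore cannot show how either setting behaves with correlated genes, and does not favour the preset one. Correlation alone does not account for the lost calls. Among the lists that lost theirs, some had an estimate below the preset 0.01. These include the fibroblast and endothelial markers (-0.023), the cholesterol and SREBP targets (-0.019) and the p53 targets (-0.037).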

Results

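The series measured mRNA levels in H4 cells, an established human neuroglioma line, on Affymetrix Human Genome U133 Plus 2.0 arrays. Control cells were set against cells transfected with a plasmid that carries Myc-tagged alpha-synuclein (aSyn), the protein that accumulates in the Lewy bodies of Parkinson disease. Each group had 2 arrays, and each of the 4 arrays was deposited in 2 summaries, RMA and MAS5, which make 8 records. After 62 AFFX control probe sets were set aside, 54613 probe sets remained, and 19775 genes had at least 1 probe set of their own. The RMA medians of the 4 arrays lay between 5.66 and 5.70 on the log2 scale. The arrays of the control pair correlated across probe sets with r = 0.998 and those of the aSyn pair with r = 0.996, against 0.986 for each of the 4 pairs between the groups. Only 2 probe sets differed by at least 2-fold between the control arrays and 75 between the aSyn arrays, while 1664 to 1846 did between a control and an aSyn array. With 2 arrays a group, the number of arrays limits the precision. The labels do not say that the samples of a group were separate cultures, so p-values measure the spread between these samples, which may be technical.

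The comparison asks how the transcriptome of H4 cells differs after transfection with Myc-tagged aSyn, whose level was not analysed here. Secreted inflammatory mediators made up much of the top of the list of rises: the chemokine CXCL8 went from 8.72 ± 0.18 in control cells to 13.08 ± 0.48 in aSyn cells (mean RMA log2 value ± SD, n = 2 arrays each, here and below), a 20.6-fold rise. CXCL3 rose 16.3-fold, IL1A 10.4-fold, the pentraxin PTX3 9.81-fold, IL6 9.22-fold, CCL20 9.19-fold and the cytokine TSLP 9.15-fold. The other genes among the 12 largest rises were KLHDC7B at 31.5-fold, the epithelial splicing regulator ESRP1 at 15.5-fold, the long noncoding RNA LINC02806 at 10.4-fold, the stress-induced pseudokinase TRIB3 at 8.89-fold and the ATP-gated channel P2RX7 at 8.35-fold. The largest fall was that of MGP, an inhibitor of calcification secreted into the matrix, from 11.99 ± 0.01 to 6.02 ± 0.45, a log2 difference of -5.97 ± 0.21 (SE). SYTL5 (-4.75) and SYTL2 (-3.28), which encode synaptotagmin-like proteins of vesicle transport, fell with it, as did LRRC17 (-4.23), TMT1A (-4.22), S100A4 (-4.05), the laminin chain LAMA4 (-3.35), GASK1B (-3.33), LRRC15 (-3.32), CRISPLD2 (-3.23), GPNMB (-3.17) and PI15 (-3.15). Adjusted p-values of these 24 genes ran from 0.000423 to 0.0149. Of the 4 probe sets of TMT1A and the 5 of LAMA4, 1 each passed, and the median levels of their probe sets differed by -0.92 and -0.58. LRRC17, GASK1B, LRRC15, CRISPLD2, PI15 and, among the rises, IL1A had 2 probe sets each, of which 1 passed. The control means of 4 of the 12 rises (KLHDC7B, IL1A, LINC02806 and CCL20) and the aSyn means of 7 of the 12 falls (SYTL5, LRRC17, TMT1A, LAMA4, GASK1B, CRISPLD2 and PI15) lay below the array medians, so the size and rank of these differences are not settled: that of CCL20 was 3.20 in RMA and 4.94 and 2.28 in MAS5 values with 1 and 16 added, and that of TMT1A -4.22, -3.72 and -2.41. The call of PI15, whose aSyn value was 4.93 ± 1.17, was lost without control replicate 1 (adjusted p 0.103) and without control replicate 2 (adjusted p 0.13).

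**Figure D1:**
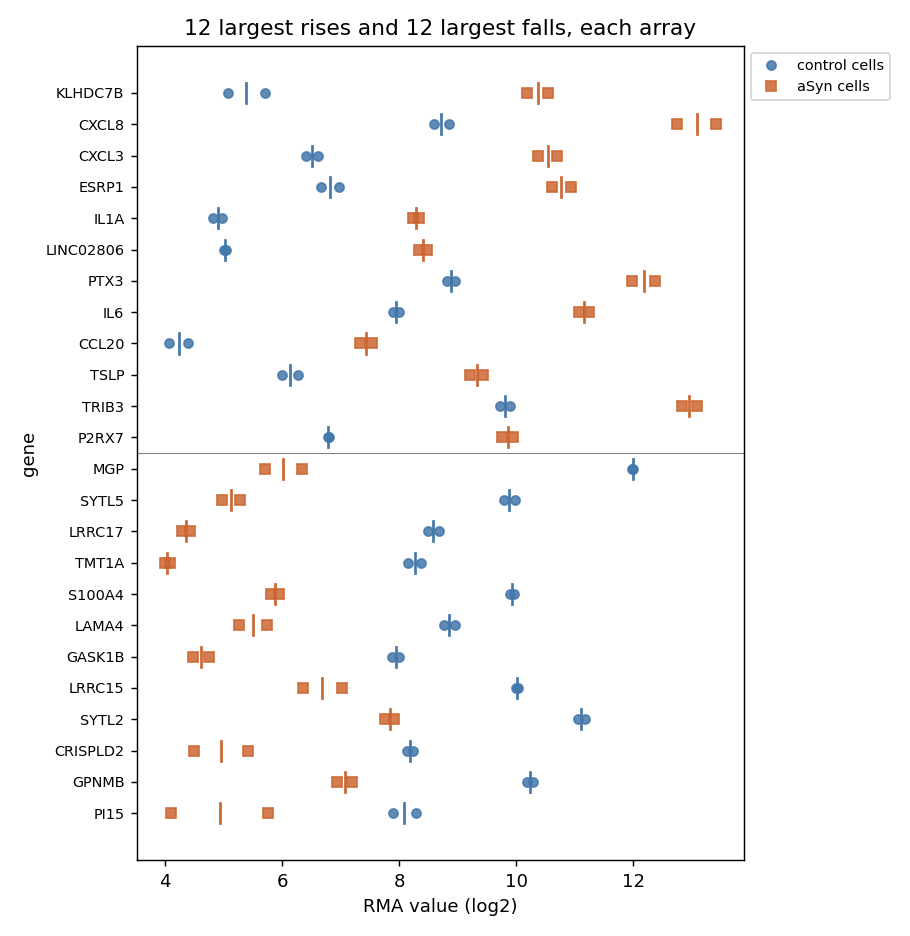
Points are the RMA values (log2, horizontal axis) of single arrays for the 12 genes with the largest rise (above the line) and the 12 with the largest fall (below it), circles for control and squares for aSyn cells, and vertical bars are the means of 2 arrays. In each gene both aSyn arrays lie on the same side of both control arrays, with MGP falling from 11.99 to 6.02 and CXCL8 rising from 8.72 to 13.08.

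Over all probe sets, 7405 of 54613 (13.6%) changed at a Benjamini-Hochberg adjusted p of 0.05 in limma's moderated test, 3469 upwards and 3936 downwards. Of these, 664 rose and 920 fell by at least 2-fold. Counted as genes, 1625 rose and 1844 fell among 19775, so that 17.5% changed. The counts of list members given below are to be read beside these counts over all genes. Both aSyn arrays lay at least 1.5-fold above both control arrays in 1421 probe sets and at least 1.5-fold below in 1863, against 3 and 1 probe sets in the other 2 ways to split the 4 arrays into pairs. On MAS5 values the count in either direction was 6008, against 2275 and 1952. Each of the other splits puts a control and an aSyn array on both sides, so that a difference between the groups works against its count. The exact test of 2 arrays against 2 cannot give a p below 0.333. With MAS5 values as log2(value + 1), limma called 0 probe sets, with 8908 at an unadjusted p under 0.05, and as log2(value + 16) it called 2834. In MAS5, 7373 of the 7405 probe sets called on RMA values (99.6%) had the same sign, as had 73.6% of those not called. The count fell to 1096 without control replicate 1, to 982 without control replicate 2 and to 4924 without aSyn replicate 2.

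**Figure D2:**
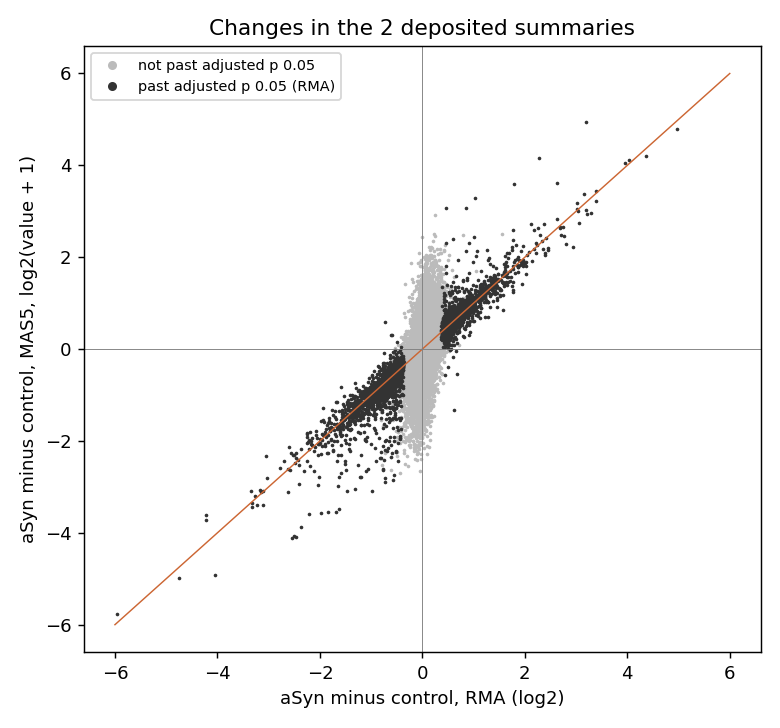
Each point is 1 of 19775 genes, with its log2 difference between aSyn and control cells in the RMA values (horizontal axis) and in the MAS5 values as log2(value + 1) (vertical axis), dark where the RMA difference passed an adjusted p of 0.05; the line marks equal values. All 1584 probe sets called at 2-fold or more on RMA values had the same sign in MAS5, and genes with small RMA differences scatter widely in MAS5.

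The NF-kB and cytokine genes, targets and mediators of inflammatory signalling, rose as a group. Of 29 measured, 16 rose, 1 fell and 12 did not pass. The median log2 difference was 0.59, and the shift against other genes had an adjusted p of 4e-07 in camera (adjusted p = 0.44 with an estimated correlation). Adjusted over the list alone, 17 rose and 1 fell. CXCL8 (log2 difference 4.36 ± 0.23, SE), CXCL3 (4.02 ± 0.14), IL1A (3.38 ± 0.10) and IL6 (3.20 ± 0.11) had the largest differences of the list. Interferon response genes, which include antiviral effectors, rose too, with 22 of 44 up, 1 down and 21 not past the threshold. Their median was 0.45, with a camera adjusted p of 4e-07 (adjusted p = 0.54 with an estimated correlation). Over this list alone, 24 rose and 2 fell. The chemokine CXCL10 rose by 2.17 ± 0.15 on the log2 scale, RSAD2 by 1.86 ± 0.11, and the antiviral GTPases MX2 and MX1 by 1.80 ± 0.14 and 1.52 ± 0.14. The second probe set of IL1A measured -0.46. The control mean of RSAD2 lay below the array medians, so the size of its rise is not settled. Fry gave the interferon list an adjusted p of 0.0514, within a range of 3.69e-10 to 0.0514 over 11 alternatives.

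In the ER stress list the members moved apart, with 15 of 31 up, 10 down and 6 not past the threshold. TRIB3 (3.15 ± 0.13), the transcription factor ATF3 (2.21 ± 0.10), the ER stress sensor ERN1 (2.13 ± 0.17) and SESN2 (1.97 ± 0.09), a stress-induced regulator of mTORC1, had the largest differences. Only 1 of the 3 probe sets of ERN1 passed, and their median level differed by 0.33. Adjusted over the list alone, 16 rose and 12 fell. The list as a whole did not pass in camera, with a median of 0.25 and an adjusted p of 0.102 (0.507 with an estimated correlation). Among 31 immediate early genes, which respond to growth factors and stress within minutes, 11 rose, 4 fell and 16 did not pass. Adjusted over the list alone, 15 rose and 6 fell. The list was shifted upwards with an adjusted p of 0.0262 (adjusted p = 0.449 with an estimated correlation). EGR1 (-2.69 ± 0.10) and FOS (-1.63 ± 0.15) went against the list and fell, while ATF3 and KLF4 (1.58 ± 0.10) rose. Ribosome biogenesis genes and MYC targets rose in 8 of 30 members, with 22 not past the threshold and 0 down (14 and 0 adjusted over the list alone). Their shift had an adjusted p of 0.000197 (adjusted p = 0.441 with an estimated correlation). MYC itself rose by 1.15 ± 0.09, RRP12 by 0.92 ± 0.13 (with 3 of its 5 probe sets higher), the rRNA methyltransferase NOP2 by 0.67 ± 0.12 and the RNA polymerase I subunit POLR1B by 0.59 ± 0.10. The median level of the RRP12 probe sets differed by -0.18. The aSyn mean of FOS lay below the array medians, so the size of its fall is not settled. None of 37 ribosomal protein genes passed, over all probe sets or over the list alone (median 0.01, adjusted p 0.605), and RPL12 at 0.34 ± 0.09 had the largest difference. The immediate early call ended without aSyn replicate 2 (adjusted p 0.0855) and among the probe sets above the median mean value (0.0614), in a range of 0.00507 to 0.0855 over 11 alternatives, and ER stress passed in 3 of its 11, among them the fit without control replicate 2 (0.0461, range 0.0121 to 0.22), and the ribosomal proteins in 2, MAS5 as log2(value + 16) (0.0234) and fry (0.0397, range 0.0234 to 0.788). Of 11 named calls here, 3 ended without control replicate 1, 4 without control replicate 2, 0 without aSyn replicate 1 and 2 without aSyn replicate 2.

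Genes of the extracellular matrix and TGF-beta targets fell, with 25 of 42 down, 6 up and 11 not past the threshold. Adjusted over the list alone, 31 fell and 7 rose. The median was -0.79 and the camera adjusted p was 9.75e-09 (adjusted p = 0.507 with an estimated correlation). The laminin chain LAMA4 (-3.35 ± 0.18), the type I collagen chain COL1A1 (-3.10 ± 0.29), the actin-binding protein TAGLN (-2.37 ± 0.14) and fibronectin, FN1 (-2.26 ± 0.13), had the largest falls of the list. Markers of fibroblasts and endothelium, a list that shares COL1A1 and COL3A1 with the matrix list, had 8 of 15 members down, 0 up and 7 not past the threshold (9 down adjusted over the list alone). Their median was -0.97, with an adjusted p of 1.4e-05 (adjusted p = 0.441 with an estimated correlation). In it S100A4 (-4.05 ± 0.10), the serine protease FAP (-2.62 ± 0.12), lumican, LUM (-1.56 ± 0.32), COL3A1 (-1.39 ± 0.25) and THY1 (-1.36 ± 0.09) fell. Cytoskeletal genes fell in 15 of 34 members, with 1 up and 18 not past the threshold (18 and 2 adjusted over the list alone). The median was -0.38, with an adjusted p of 9.68e-06 (adjusted p = 0.481 with an estimated correlation). The microtubule-associated protein MAP1A (-1.56 ± 0.12), tropomyosin TPM1 (-1.41 ± 0.11) and the tubulins TUBB2A (-1.10 ± 0.10) and TUBA1A (-1.03 ± 0.10) fell. The difference of the 5' and 3' probe sets of ACTB, a measure of RNA integrity, was -0.89 in both control arrays and -1.39 and -0.97 in the aSyn arrays, and that of 18S ribosomal RNA was -0.10 and -0.15 in control and -1.35 and -0.89 in aSyn arrays. Probe sets of COL1A1 ranged from -3.29 to 0.25 and those of LAMA4 from -3.35 to -0.13. Only 1 of the 3 probe sets of MAP1A passed, and their median level differed by -0.52. The aSyn mean of FAP lay below the array medians, so the size of its fall is not settled. Of the 13 named calls, 3 were lost without control replicate 1, 4 without control replicate 2, 0 without aSyn replicate 1 and 0 without aSyn replicate 2.

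**Figure D3:**
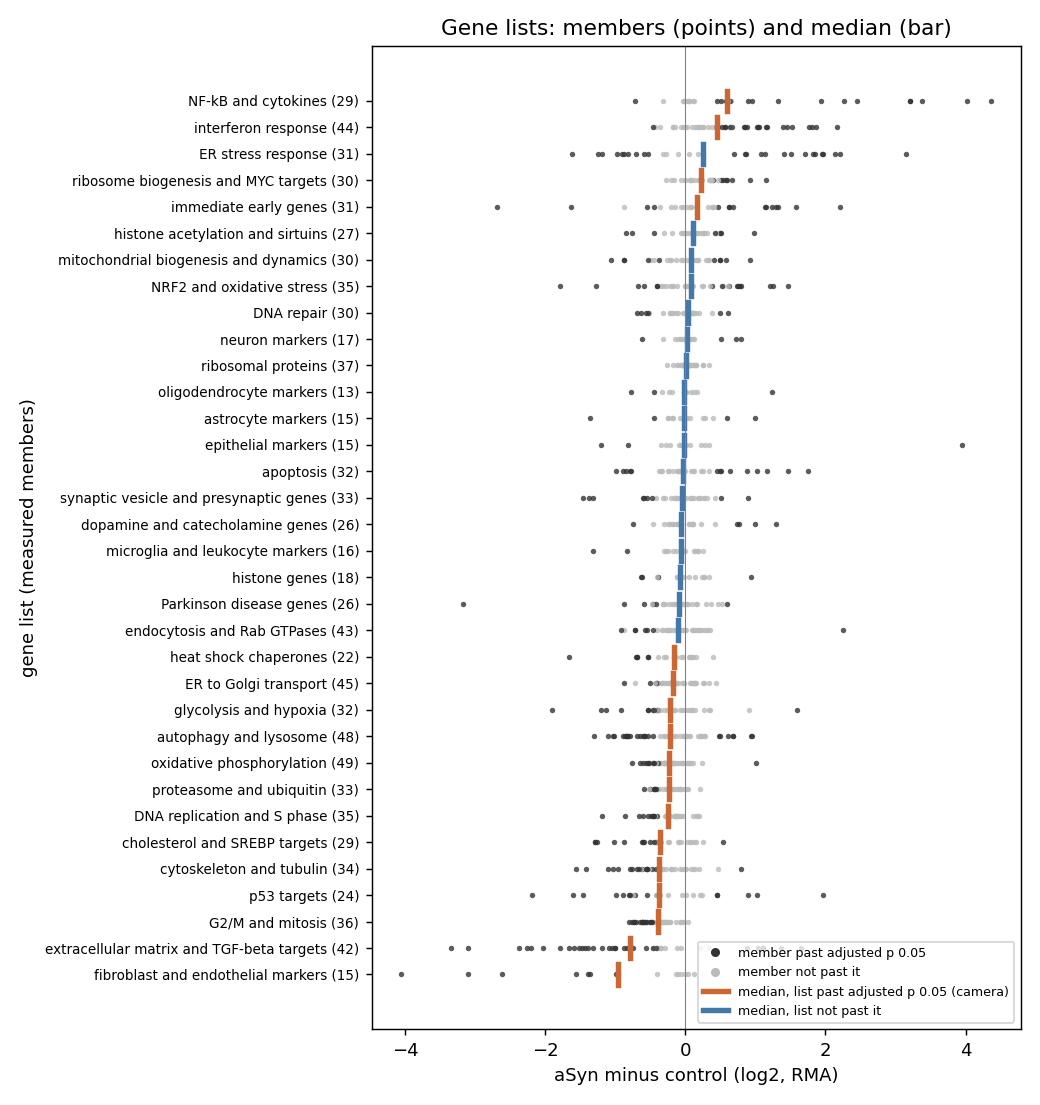
Each point is a member of 1 of 34 gene lists, placed by its log2 difference between aSyn and control cells (RMA values), dark where it passed an adjusted p of 0.05; bars are list medians, orange where the list passed in camera with a preset correlation, and brackets hold the number of measured members. Medians run from -0.97 for the fibroblast and endothelial markers to 0.59 for the NF-kB and cytokine genes, and 17 lists passed.

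Cell cycle genes were lower in aSyn cells. Whether the weaker 5' signal of the aSyn RNA plays a part in this or in the lists below was not tested. Of 36 genes of G2/M and mitosis, 16 fell, 0 rose and 20 did not pass (24 fell when adjusted over the list alone). The median was -0.39, with an adjusted p of 1.82e-09 (adjusted p = 0.441 with an estimated correlation). The mitotic kinesins KIF11 (-0.81 ± 0.16) and KIF20A (-0.77 ± 0.10), the spindle factor TPX2 (-0.74 ± 0.15) and topoisomerase TOP2A (-0.73 ± 0.10) fell. Of 35 genes of DNA replication and S phase, 10 fell, 0 rose and 25 did not pass (11 fell when adjusted over the list alone). Their median was -0.25, with an adjusted p of 1.56e-05 (adjusted p = 0.441 with an estimated correlation). Thymidine kinase, TK1 (-1.19 ± 0.09), the transcription factor E2F8 (-0.87 ± 0.11), GINS2 (-0.67 ± 0.11) and thymidylate synthase, TYMS (-0.61 ± 0.09), fell. The p53 targets were shifted downwards, with 10 of 24 down, 5 up and 9 not past the threshold (14 and 5 adjusted over the list alone). Their median was -0.38 and the adjusted p 0.0204 (adjusted p = 0.441 with an estimated correlation). Among them TP53I3 (-2.19 ± 0.09), DDB2 (-1.60 ± 0.13) and TP53INP1 (-1.45 ± 0.09, with 1 of its 3 probe sets lower) fell, and SESN2 (1.97 ± 0.09) rose. In the DNA repair list 4 of 30 fell, 2 rose and 24 did not pass, with the same counts adjusted over the list alone. The list did not pass, with a median of 0.03, a mean of -0.06 and an adjusted p of 0.551. Its largest differences were those of DNA ligase LIG1 (-0.69 ± 0.15), FANCI (-0.63 ± 0.09), RAD50 (0.61 ± 0.10) and RAD51AP1 (-0.56 ± 0.11). The median level of the 3 probe sets of FANCI differed by -0.16. Histone genes had 3 of 18 members down, 1 up and 14 not past the threshold (4 and 1 adjusted over the list alone) and an adjusted p of 0.551. The linker histone H1-10 (0.93 ± 0.09) rose, H2BC5 (-0.63 ± 0.10) and H4C8 (-0.62 ± 0.13) fell, and H2AZ2 measured -0.40 ± 0.10. H2BC5 and H4C8 had 2 probe sets each, of which 1 passed. In MAS5 values with 1 and 16 added, H4C8 differed by only -0.12 and -0.078. The p53 call ended in the 3 MAS5 settings and without aSyn replicate 1 (adjusted p 0.0523), in a range of 0.00659 to 0.111 over 11 alternatives. For 19 named genes that passed here, 14 calls were lost without control replicate 1, 14 without control replicate 2, 4 without aSyn replicate 1 and 5 without aSyn replicate 2.

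Genes of cholesterol synthesis and other SREBP targets fell in 11 of 29 members, with 1 up and 17 not past the threshold (16 and 1 adjusted over the list alone). The median was -0.36, with an adjusted p of 1.97e-05 (adjusted p = 0.441 with an estimated correlation). The sterol isomerase EBP (-1.29 ± 0.10), the sterol carrier STARD4 (-1.29 ± 0.10), ACAT2 (-1.26 ± 0.10) and lanosterol synthase, LSS (-1.02 ± 0.11), fell. Oxidative phosphorylation genes were shifted downwards by smaller amounts, with 9 of 49 down, 1 up and 39 not past the threshold (10 and 1 adjusted over the list alone). Their median was -0.23, with an adjusted p of 9.11e-06 (adjusted p = 0.481 with an estimated correlation). The ATP synthase subunits ATP5MG (-0.77 ± 0.09) and ATP5MC1 (-0.65 ± 0.12) and the complex I subunit NDUFB3 (-0.60 ± 0.11) fell. Only 1 of the 4 probe sets of ATP5MG passed, and their median level differed by -0.27. The ATP synthase subunit ATP5F1C (1.00 ± 0.13) rose and had the largest difference of the list, but 3 of its 4 probe sets were lower. Glycolysis and hypoxia genes fell in 10 of 32 members, with 1 up and 21 not past the threshold (15 and 4 adjusted over the list alone). The median was -0.21, with an adjusted p of 0.00838 (adjusted p = 0.507 with an estimated correlation). The prolyl hydroxylase EGLN3 (-1.90 ± 0.12), PFKFB4 (-1.21 ± 0.10) and aldolase ALDOC (-1.13 ± 0.17) fell, and the glucose transporter SLC2A3 (1.60 ± 0.09) rose. Of the 2 probe sets of PFKFB4, 1 passed. NRF2 and oxidative stress genes went both ways, with 10 of 35 up, 6 down and 19 not past the threshold (12 and 8 adjusted over the list alone) and an adjusted p of 0.454. Heme oxygenase HMOX1 (1.25 ± 0.10) and OSGIN1 (1.46 ± 0.12) rose, and GPX3 (-1.79 ± 0.26) and AKR1B10 (-1.28 ± 0.11) fell. Mitochondrial biogenesis and dynamics genes had 5 of 30 members up, 5 down and 20 not past the threshold (5 and 6 adjusted over the list alone). The list did not pass, with a median of 0.08, a mean of -0.02 and an adjusted p of 0.909, and TIMM44 (0.93 ± 0.09) rose while PPARGC1A (-1.07 ± 0.15) and FIS1 (-0.87 ± 0.14) fell. Both means of PPARGC1A lay below the array medians, so the size of its difference is not settled. It was -1.49 and -0.71 in MAS5 values with 1 and 16 added. The other probe set of PPARGC1A measured 0.097. The glycolysis call ended in 4 of 11 alternatives, among them MAS5 as log2(value + 1) (adjusted p 0.122) and the fit without aSyn replicate 1 (0.0717), in a range of 0.00111 to 0.122, and the NRF2 list passed in fry alone (0.025, range 0.025 to 0.648). The 19 named calls lost 9 members without control replicate 1, 10 without control replicate 2, 0 without aSyn replicate 1 and 2 without aSyn replicate 2.

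Lists of protein handling were lower in aSyn cells, each by a small amount. Proteasome and ubiquitin genes had 6 of 33 members down, 0 up and 27 not past the threshold (8 down adjusted over the list alone). Their median was -0.23 and the adjusted p 2.28e-05 (adjusted p = 0.441 with an estimated correlation). The proteasome subunits PSMD3 (-0.59 ± 0.10), PSMD2 (-0.50 ± 0.10) and the segregase VCP (-0.45 ± 0.10) fell, and UBA1 measured -0.52 ± 0.27. Autophagy and lysosome genes went down in 18 of 48 and up in 7, with 23 not past the threshold (21 and 8 adjusted over the list alone). Their median was -0.22, with an adjusted p of 0.006 (adjusted p = 0.481 with an estimated correlation). Acid sphingomyelinase, SMPD1 (-1.30 ± 0.09), CTSA (-1.10 ± 0.10), the cholesterol-binding protein NPC2 (-1.03 ± 0.09) and cathepsin D, CTSD (-1.02 ± 0.14), fell. Heat shock chaperones fell in 6 of 22 members, with 0 up and 16 not past the threshold (6 down and 1 up adjusted over the list alone). The median was -0.16 and the adjusted p 0.0152 (adjusted p = 0.519 with an estimated correlation). The small heat shock proteins HSPB1 (-1.66 ± 0.17), HSPB8 (-0.70 ± 0.09) and CRYAB (-0.69 ± 0.12) and the co-chaperone DNAJB1 (-0.70 ± 0.09) fell. ER to Golgi transport genes had 4 of 45 down, 0 up and 41 not past the threshold (1 down adjusted over the list alone). Beside 1844 of 19775 genes down in all, these genes had no larger share of falls. Their median was -0.18 and the adjusted p 0.00666 (adjusted p = 0.519 with an estimated correlation), and the ER retrieval receptor KDELR3 (-0.87 ± 0.09) and RAB1B (-0.50 ± 0.11) fell. TRAPPC1 measured -0.71 ± 0.20 and ARF1 0.44 ± 0.15, which did not pass. Endocytosis and Rab genes did not pass, with 6 of 43 down, 1 up and 36 not past the threshold (6 and 2 adjusted over the list alone) and an adjusted p of 0.197. RAB39B, a small GTPase gene mutated in early-onset parkinsonism, rose 4.73-fold, from 6.32 ± 0.02 to 8.57 ± 0.04. Dynamin DNM1 (-0.92 ± 0.10) and the adaptor subunit AP2A1 (-0.72 ± 0.16) fell, and AP2M1 measured -0.87 ± 0.25. Only 1 of the 4 probe sets of AP2A1 passed, and their median level differed by -0.16. The other probe set of DNM1 measured 0.075. Of the 4 probe sets of SMPD1 2 passed (median level -0.38), and of the 2 of HSPB8 1 passed. The aSyn means of AP2A1 and CRYAB lay below the array medians, so the sizes of their falls are not settled. Leaving out aSyn replicate 1 ended the autophagy (adjusted p 0.0523, range 0.00111 to 0.0523 over 11 alternatives), heat shock (0.0713, range 0.00572 to 0.122) and ER to Golgi (0.16, range 0.000169 to 0.16) calls. Fry also ended the ER to Golgi call (0.136), and the heat shock call was lost in 6 of 11 alternatives in all, the others being the 3 MAS5 settings, the probe sets above the median mean value (0.0813) and fry (0.0688). Among the 16 named genes that passed here, 13 did not without control replicate 1, 14 without control replicate 2, 2 without aSyn replicate 1 and 5 without aSyn replicate 2.

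Of 26 genes linked to Parkinson disease, 5 fell, 1 rose and 20 did not pass (9 and 5 adjusted over the list alone), and the list did not pass, with an adjusted p of 0.194. GPNMB, at a risk locus (-3.17 ± 0.12), the mitochondrial kinase gene PINK1 (-0.87 ± 0.14) and SYNJ1 (-0.59 ± 0.12) fell, and DNAJC6 (0.59 ± 0.13) rose. In the presynaptic list 7 of 33 fell, 2 rose and 24 did not pass (8 and 2 adjusted over the list alone), with an adjusted p of 0.243. RIMS1 (-1.46 ± 0.13), AMPH (-1.37 ± 0.10) and SYNGR1 (-1.32 ± 0.11) had the largest falls, and SYN2 (0.90 ± 0.09, with 4 of its 5 probe sets higher) and SYT1 (0.51 ± 0.09) rose. Only 1 of the 5 probe sets of SYN2 passed, and their median level differed by -0.23. Of the 3 probe sets of SYNGR1, 1 passed, and their median level differed by -0.33. SYT1 and DNAJC6 had 2 probe sets each, of which 1 passed. The aSyn mean of RIMS1 lay below the array medians, so the size of its fall is not settled. Dopamine and catecholamine genes rose in 4 of 26 and fell in 1, with 21 not past the threshold (4 and 2 adjusted over the list alone). The median was -0.06, the mean 0.07 and the adjusted p 0.962. The nuclear receptor NR4A2 rose by 1.29 ± 0.16, EN2 by 0.99 ± 0.13, the receptor DRD5 by 0.76 ± 0.11 and GTP cyclohydrolase, GCH1, by 0.74 ± 0.09. Both means of DRD5 and the control mean of NR4A2 lay below the array medians, so the sizes of these rises are not settled. In MAS5 values with 1 and 16 added, DRD5 differed by 0.78 and 0.37 and NR4A2 by 1.98 and 0.87. Apoptosis genes rose in 9 of 32 and fell in 5, with 18 not past the threshold (10 and 7 adjusted over the list alone). The median was -0.04, the mean 0.09 and the adjusted p 0.762. The BH3-only gene HRK (1.75 ± 0.12), the anti-apoptotic BCL2 (1.46 ± 0.10), CASP4 (1.16 ± 0.10) and the death receptor TNFRSF10B (1.02 ± 0.10) rose. Probe sets of HRK ranged from -0.14 to 1.75 and those of BCL2 from 0.04 to 1.46, with 1 of the 4 of BCL2 past the threshold. The control mean of HRK lay below the array medians. Histone acetyltransferases, deacetylases and sirtuins rose in 4 of 27 and fell in 3, with 20 not past the threshold, the same counts adjusted over the list alone and an adjusted p of 0.243. HDAC9 (0.98 ± 0.10) and HDAC4 (0.50 ± 0.09) rose, and HDAC8 (-0.85 ± 0.12) and KAT2B (-0.77 ± 0.14) fell. Only 1 of the 5 probe sets of HDAC9 passed, and their median level differed by 0.045. The aSyn mean of KAT2B lay below the array medians, and its difference was -0.31 and -0.20 in MAS5 values with 1 and 16 added. The histone acetylation list passed in fry alone (0.0359, range 0.0359 to 0.625). There were 21 named calls, of which 14 ended without control replicate 1, 14 without control replicate 2, 4 without aSyn replicate 1 and 5 without aSyn replicate 2.

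Marker lists of other cell types, fixed as a check of the cultures, did not pass apart from that of fibroblasts and endothelium. Of 16 microglia and leukocyte markers, 0 rose and 2 fell, with 14 not past the threshold and the same counts adjusted over the list alone (median -0.07, adjusted p 0.283). LCP1 (-1.32 ± 0.12) and HLA-DRA (-0.84 ± 0.11) fell. Of 15 astrocyte markers, 2 rose, 2 fell and 11 did not pass (3 and 2 adjusted over the list alone, list adjusted p 0.98), with GLUL (1.00 ± 0.09) and SLC1A3 (0.59 ± 0.10) up and CLU (-1.37 ± 0.20) and GJA1 (-0.44 ± 0.09) down. Of 17 neuron markers, 3 rose, 1 fell and 13 did not pass (list adjusted p 0.832), with MAP2 (0.80 ± 0.14), RBFOX3 (0.72 ± 0.17) and SYT1 up and TUBB3 (-0.62 ± 0.09) down. Of 13 oligodendrocyte markers, 1 rose, 2 fell and 10 did not pass (list adjusted p 0.663), with OLIG2 (1.24 ± 0.09) up and PDGFRA (-0.77 ± 0.12) and CNP (-0.44 ± 0.10) down. Both lists had the same counts adjusted over the list alone. Of 15 epithelial markers, ESRP1 alone rose, KRT8 (-1.20 ± 0.11) and CLDN4 (-0.82 ± 0.15) fell and 12 did not pass (1 up and 3 down adjusted over the list alone, list adjusted p 0.656). Only 1 of the 4 probe sets of PDGFRA passed, and their median level differed by -0.056. OLIG2, CNP, SLC1A3, SYT1 and CLDN4 had 2 probe sets each, of which 1 passed, and RBFOX3 had 3, of which 1 passed. The control mean of RBFOX3 and the aSyn means of HLA-DRA and CLDN4 lay below the array medians. The sizes of these 3 differences are therefore not settled. The 5' minus 3' difference of GAPDH was -0.09 in both control arrays and -0.25 and -0.10 in the aSyn arrays. Named calls in these lists numbered 16, of which 13, 14, 4 and 6 were lost without control replicate 1, control replicate 2, aSyn replicate 1 and aSyn replicate 2.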

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

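Chosen only after the results were seen were the tests of the summary method, of a general fall of abundant genes, of plasmid DNA by itself, of leukocytes or microglia, and of the weaker 5' signal behind the inflammatory genes.

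A control probe set outside the comparison was higher in both aSyn arrays: the middle probe set of 28S ribosomal RNA read 10.56 ± 0.04 in control and 11.09 ± 0.02 in aSyn cells, a difference of 0.53 in RMA values and of 0.11 in MAS5 values, while the 5' probe set of the same RNA differed by -0.38.

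Between the groups 7405 probe sets changed. If the groups were sublines that differ in chromosome copy number, blocks of neighbouring genes would shift together. Of 274 windows of 50 neighbouring genes, 1 lay beyond the 95th percentile of the largest window median over 1000 random gene orders (a median of -0.25 relative to all genes), where at least 3 had been set as the sign of such a difference, which argues against large copy number differences as the main source. The SD of the window medians, 0.0621, was above the highest of the random orders, 0.0556, so small regional differences stay open. The part of the summary method stays open: 99.6% of the called probe sets had the same sign in MAS5 values, against 73.6% of the others, but they were picked by their RMA difference on the same arrays, and limma called 0 on MAS5 log2(value + 1) and 2834 on log2(value + 16).

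NF-kB, cytokine and interferon genes were higher in aSyn cells, by medians of 0.59 and 0.45. Leukocytes or microglia in the aSyn cultures would bring their own markers, which had a median of -0.067 with 0 of 16 past the threshold upwards. The weaker 5' signal of the aSyn RNA stays open. The NF-kB median lay 0.57 above that of all probe sets, which is the rise in question. The NF-kB and interferon medians were 0.47 and 0.37 in aSyn replicate 1 and 0.71 and 0.53 in replicate 2, which had less 5' loss in ACTB. But 1 array decides that comparison, and the 5' signal of 18S ribosomal RNA was lower in both aSyn arrays. The middle probe set of 18S fell by more than its 5' one (-1.37 against -1.20 in RMA values). The 18S change was thus not a loss at the 5' end alone. Also open is the plasmid DNA itself: interferon genes rose together with the cytokines (median 0.45), which foreign DNA may cause without aSyn, and the labels name no group that received an empty plasmid, so this and an effect of aSyn cannot be told apart.

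Matrix genes and fibroblast markers were lower in aSyn cells. Whether every abundant gene fell, from saturation or scaling, cannot be decided here. Each MAS5 column has the same trimmed mean (100.01), which would largely remove a fall shared by abundant genes. Relative to other genes of the same level the 55 genes were lower, with a median of -0.87 in MAS5 values. Medians of 10000 random lists matched on the mean value ran from -0.30 to 0.26, the middle one 9.00e-05. That middle value near 0 is largely set by the shared trimmed mean, but the lower place of the 55 genes is not. A weaker 5' signal of the aSyn RNA cannot be told apart from a biological difference: the median fall in aSyn replicate 2 was 0.76 times that in replicate 1 (-0.64 against -0.85), although the 5' loss of ACTB was -0.09 against -0.50. That comparison rests on a single array with little loss in ACTB, so the similar falls do not decide. The 5' signal of 18S ribosomal RNA was lower in both aSyn arrays, but its middle probe set fell by more (-1.37 against -1.20). An effect of aSyn, the difference the design names, remains untested against a weaker 5' signal.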

How the results depend on the processing

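All alternatives were set before the data were examined. Against 7405 probe sets called on RMA values, limma called 0 on MAS5 values as log2(value + 1) and 0 after quantile normalization of these, with 8908 at an unadjusted p under 0.05 in the former. It called 2834 on log2(value + 16), of which 2693 were shared, 4726 with a fold threshold of 1.5, and 982 to 5272 with 1 array left out, of which 979 and 4614 were shared. Genes went from 3469 to 0, 0, 1485 and 2147 under the same settings and to 528 to 2401 with 1 array left out. The fits without control replicate 1, control replicate 2 and aSyn replicate 2 moved the count by over 1.5 times. All fits with 1 array left out have the same number of arrays, so fewer samples alone do not account for the larger drop without a control array. In those fits the spread is taken from the aSyn pair, whose SD of difference was 0.235, against 0.172 in the control pair. Many calls thus depend on the small spread of the control pair. Probe sets apart in every array pair went from 3284 to 6008 on MAS5 values (2275 and 1952 in the other splits), 6004 after quantile normalization and 1137 at 2-fold. The cause of the MAS5 differences was not tested. Of 17 lists, 0 passed with an estimated correlation. The replicate numbers do not pair the samples as far as the labels say. Across probe sets, control 1 minus control 2 correlated with aSyn 1 minus aSyn 2 at 0.209, so a part shared by replicate number stays open. With the replicate block 5956 probe sets were called. With the median level of all probe sets of a gene in each array, 12 named calls were lost with the direction kept. Another 4 named genes turned direction: TP53INP1 to 0.047, ATP5F1C to -0.29, SYN2 to -0.23 and RRP12 to -0.18. The medians of the differences of their single probe sets were 0.047, -0.27, 0.30 and 0.015. Of the 154 genes under the naming rule 136 had passed, and of these calls all 136 were lost on MAS5 values as log2(value + 1), 37 on log2(value + 16), 10 under the block, 69 and 74 without control replicates 1 and 2, and 13 and 24 without aSyn replicates 1 and 2. The trend and robust prior was not run for the lists, and the transfected gene was not analysed. The array medians of the MAS5 values were 13.8 to 14.7, and the effect of low signal over background was not tested.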

Other observations

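The hypotheses here came from the results above. Their 3 gene lists were written after those results were seen and before the values of their own members were. They leave out every member of the earlier lists and were adjusted over the 3 lists. The sign set in advance for each was a camera adjusted p below 0.05 in the direction named, which all 3 lists met. That most members must also pass was required only after these results were seen, and it left 2 of the 3 undecided. The genes named here were chosen after their values were seen.

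Members of the ER stress list that passed went both ways, and no division of the list was fixed or tested. Among the 15 that rose were PPP1R15A (log2 difference 1.95 ± 0.11, SE), ASNS (1.85 ± 0.10), DDIT3, which encodes CHOP (1.82 ± 0.09), CHAC1 (1.71 ± 0.11) and ATF4 (1.14 ± 0.09), genes of the ATF4 and CHOP branch, and also XBP1 (1.08 ± 0.19) of the ERN1 branch and the ER co-chaperone gene DNAJB9 (0.85 ± 0.09). Among the 10 that fell were CALR (-1.61 ± 0.21), CRELD2 (-1.25 ± 0.10), SDF2L1 (-1.19 ± 0.12), PDIA3 (-0.97 ± 0.11), MANF (-0.90 ± 0.09), PDIA4 (-0.88 ± 0.09) and HSP90B1 (-0.82 ± 0.09). HSPA5, the main ER chaperone, measured 0.06 ± 0.10.

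A candidate explanation is that the amino acid response, which ATF4 drives, was active as a programme. Of 33 measured genes listed for this response, which include genes of amino acid synthesis, amino acid transport and tRNA charging as well as other reported targets, 28 rose, 0 fell and 5 did not pass. The median was 0.88 in RMA and 1.06 in MAS5 values, with a camera adjusted p of 1.57e-17 (adjusted p = 0.144 with an estimated correlation). PCK2 rose by 1.43, CEBPG by 1.31, NUPR1 by 1.30, the transporters SLC3A2 and SLC7A5 by 1.22 and 1.21, PHGDH, which opens serine synthesis, by 1.21 and the tRNA synthetase gene AARS1 by 1.19. Without control replicate 1 or control replicate 2, 9 members passed in each case, with 28 without aSyn replicate 1 and 24 without aSyn replicate 2. The highest adjusted p of the list over these fits was 2.92e-14. The list was written after ATF4 and genes of its branch were seen to rise on the same arrays, so its rise is not independent support. It does not tell an amino acid response from ATF4 activity in ER stress. ATF4 activity was not measured, and an effect of the transfection by itself stays open here as for the inflammatory genes.

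Whether the folding machinery of the ER was lower beyond these genes was not settled. Of 39 further genes of ER folding and translocation, 9 fell, 0 rose and 30 did not pass, with a median of -0.135 and an adjusted p of 0.00462 (adjusted p = 0.333 with an estimated correlation), which became 0.0552 without aSyn replicate 1. The 9 falls became 0 without control replicate 1, 0 without control replicate 2, 3 without aSyn replicate 1 and 5 without aSyn replicate 2. GANAB (-0.80), PPIC (-0.61) and FKBP7 (-0.58) had the largest falls. Most members did not pass, so a fall of the machinery as a whole was not shown.

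The fall of EGR1, FOS, TAGLN and TPM1, all known targets of SRF and its cofactors, raised the question whether SRF targets were lower as a group. Of 26 further targets, 11 fell, 2 rose and 13 did not pass, with a median of -0.12 and an adjusted p of 0.00745 (adjusted p = 0.144 with an estimated correlation), which became 0.0552 without aSyn replicate 1. The 11 falls became 1 without control replicate 1, 1 without control replicate 2, 6 without aSyn replicate 1 and 6 without aSyn replicate 2, and the 2 rises became 1, 1, 3 and 1. MYLK (-1.44), CALD1 (-0.99) and PDLIM7 (-0.77) fell, while ANKRD1 rose by 1.77 and MICAL2 by 0.72, and 13 members did not pass, so whether SRF targets were lower as a group stays open.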
